A study of Homo sapiens with 26 samples.

How the data were processed

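Libraries treated with RNase R and poly(A)+ libraries were made from HEK293 cells, from HEK293 cells with an SRSF1 or control hairpin, and from SH-SY5Y cells on days 0, 3 and 6 of differentiation with retinoic acid and less serum, per the labels. Groups and replicate numbers were taken from the labels. The submitters' processing notes name cutadapt, STAR, RSEM and BWA and the genome build GRCh38 (hg38). Their versions, the circRNA caller and the rule that made a circRNA an EIciRNA are not given in the sources used here.

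The HEK293 circRNA and EIciRNA tables and the SH-SY5Y EIciRNA table held counts, which the authors deposited as whole numbers of back-splice junction reads per circRNA or EIciRNA and library. The SH-SY5Y table listed values of at least 1, with the same EIciRNAs in both libraries of a day, and only EIciRNAs listed on all 3 days entered the tests. The gene tables held expected counts that the authors deposited without normalization, and RSEM is named in the submitters' processing notes. They were rounded to whole numbers. The columns of the gene tables do not state the library type, and they were taken as poly(A)+ libraries. The EIciRNA table of the knockdown experiment held a signal that the authors deposited as junction reads divided by 1 factor per library. Every value was a whole multiple of its library's step (100% of values within a tolerance of 0.01), so whole reads could be recovered. The design had assumed counts for this table, and limma on log2(signal + 1) was used instead, with edgeR on the recovered reads added after the data were seen. Fold changes on that scale understate the change of low values. IR ratios were fractions from 0 to 1 that the authors made with IRFinder, per the file headers, as intron depth over intron depth plus spliced reads. The comparison of hairpins pooled 2 libraries per hairpin, per the file headers, and its deposited p-values equal the smaller of 2 one-sided values. They were doubled, and 147 introns with a code in place of a p-value were left out.

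Gene identifiers are Ensembl identifiers, and 60370 of 60624 had a symbol in the names table used here, after the counts of 45 pseudoautosomal Y copies had been added to their X copies. Introns, exons and hosts came from GENCODE release 44 on GRCh38, and sequences from the GRCh38 genome. Of the 1535 EIciRNA introns of HEK293, 1532 matched an annotated intron exactly. Gene tests used edgeR 4.0.16 in R 4.3.3 with filterByExpr, TMM scaling, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The 3 SH-SY5Y days shared 1 fit. The 2 shCtrl gene columns were identical in all 60669 rows and entered as 1 library. EIciRNAs were tested in the same way, or with limma 3.58.1 for the knockdown. The library size in the edgeR tests was the number of reads of the EIciRNAs tested, since the total of circular reads was not used here for those libraries. Gene lists (18 in HEK293 and 27 in SH-SY5Y) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera uses the residual degrees of freedom of the fit, which are the libraries beyond the number of groups. There was 1 in the knockdown and there were 3 in SH-SY5Y, so hardly any list can pass. That test therefore cannot decide whether correlation between genes accounts for a list. Introns and exons were compared by permutation tests with 100000 resamples, and shares by Fisher's exact test. Host genes and retained introns were set against 10000 random lists matched on expression in 20 bins, on length, or both. Intervals are exact binomial intervals at 95%. A fold against a group without counts used a floor of 3 counts over the group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyfaidx 0.9.0.4 and matplotlib 3.10.9 was used for the rest.

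Genes were named by a rule fixed before the data were examined, as were the gene lists, the tests and all alternatives not said to be added later. For each gene comparison the text names the target and the 8 genes with the largest fold change in each direction among those called. These had at least 5 CPM on average and separate library ranges. From each list with a called member or a passing test, up to 4 members with the smallest p were eligible. For EIciRNAs the 8 with the smallest p in each direction were eligible, or 3 that did not pass, and in the catalogue the 8 with the most reads. For intron retention the 8 largest changes in each direction were taken. Gene names in host lists and tables of shared introns follow counts and were chosen after their values were seen.

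On simulated counts for the real genes with 200 changed genes, the gene test recovered 59% of 4-fold changes in the knockdown, 84% on day 3, 85% on day 6 and 84% between day 6 and day 3. It recovered 6%, 22%, 8% and 12% of 2-fold changes. For knockdown EIciRNAs, limma recovered 100% of 5 simulated 8-fold changes among 25, and for SH-SY5Y EIciRNAs edgeR recovered 58.3% of 12 simulated 4-fold changes among 64. The knockdown simulation gave all EIciRNAs 1 fixed spread, whereas real values could differ far more between libraries of one hairpin (23.2 and 244 for CAMSAP1 in shCtrl). Its 100% therefore does not show that an 8-fold change would have been found in the real libraries. Alternatives were median-of-ratios scaling, library size scaling, DESeq2 1.42.0, no filter and a stricter filter, a fit of the compared days only, the replicate number as a block, other pseudocounts, other matching rules and backgrounds, and leaving out each library in turn. Those added after the data were seen were counting both identical control columns, edgeR on recovered reads, the pseudocount of 0.5, sums per circRNA, undoubled p-values, GC content within bins of intron length, retained introns under 1000 bp or above 0 in both libraries, single replicates of named introns and leaving out libraries of the catalogue. The motif comparison of EIciRNAs that changed after knockdown was not made, since none passed. The EIciRNA test of day 3 against day 0 is not reported here.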

Results

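Exon-intron circular RNAs (EIciRNAs) are circular RNAs (circRNAs) that keep an intron between their exons. They were counted in 3 settings: the human embryonic kidney line HEK293, HEK293 cells carrying a short hairpin RNA against the splicing factor SRSF1 (shSRSF1) or a control hairpin (shCtrl), and the human neuroblastoma line SH-SY5Y on days 0, 3 and 6 of neuronal differentiation with retinoic acid in low serum. Circular RNA was read in libraries treated with RNase R, an exonuclease that degrades linear RNA, and linear RNA in poly(A)+ libraries. There were 4 RNase R and 2 poly(A)+ libraries of unmodified HEK293, and 2 libraries of each kind per hairpin and per day. The 4 HEK293 RNase R libraries held 310847, 407173, 306722 and 313296 back-splice junction reads, the reads that span the point where a circle closes. Of these, 2696, 3670, 2198 and 2735 belonged to EIciRNAs. The knockdown experiment held 1048 and 2652 EIciRNA reads in the shCtrl libraries and 1026 and 3033 in the shSRSF1 libraries. The SH-SY5Y RNase R libraries held 733 and 2150 EIciRNA reads on day 0, 945 and 2228 on day 3, and 2203 and 4239 on day 6. Gene counts came to 11627264 for shCtrl, 11864208 and 10901374 for shSRSF1, 10881950 and 11611630 for SH-SY5Y on day 0, 10502225 and 11517140 on day 3, and 10244324 and 11365618 on day 6. The 2 shCtrl gene count columns were identical for every gene and were therefore counted as 1 library. The labels do not say whether replicates were separate cultures, so p-values of tests between libraries measure the spread between these libraries, which may be technical. Intervals cover counting error only.

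The HEK293 catalogue addressed which circRNAs hold an intron and how abundant they are. CAMSAP1, which encodes a protein that binds microtubule minus ends, gave the most abundant EIciRNA, with 184.5 ± 58.9 reads per library (SD, n = 4). This circle lies on chromosome 9 at 135881633 to 135883078 (GRCh38) and keeps intron 2 of 16, a stretch of 1021 bp at 135881795 to 135882815. A circle of GCN1, an activator of the amino acid stress kinase GCN2, followed with 89.5 ± 26.4 reads (SD, n = 4), on chromosome 12 at 120154970 to 120155719 with intron 29 of 57. The next were EXOSC1, a subunit of the RNA exosome, with between 33 and 73 reads per library, and BABAM1, a member of a BRCA1 complex, with 44.25 ± 7.37 reads (SD, n = 4). NDUFA10, a subunit of respiratory complex I, had 40.5 ± 26.6 reads and MARK4, a kinase of microtubule-associated proteins, had 38.0 ± 18.7 (SD, n = 4 each). The centrosomal gene CEP72 and the O-mannosyltransferase gene POMT1 completed the 8 highest, with 36.0 ± 21.0 reads (SD, n = 4) and between 19 and 46 reads per library. The share of a circle's reads that held the intron separated these EIciRNAs. It was 79.4% ± 14.6 for EXOSC1, 74.9% ± 8.22 for BABAM1 and 75.8% ± 6.92 for MARK4, against 8.07% ± 0.86 for CAMSAP1, 6.40% ± 0.47 for GCN1 and 3.91% ± 2.21 for CEP72 (SD, n = 4 each). POMT1 varied most among the 8, from 36.6% to 97.9% between libraries.

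**Figure D1:**
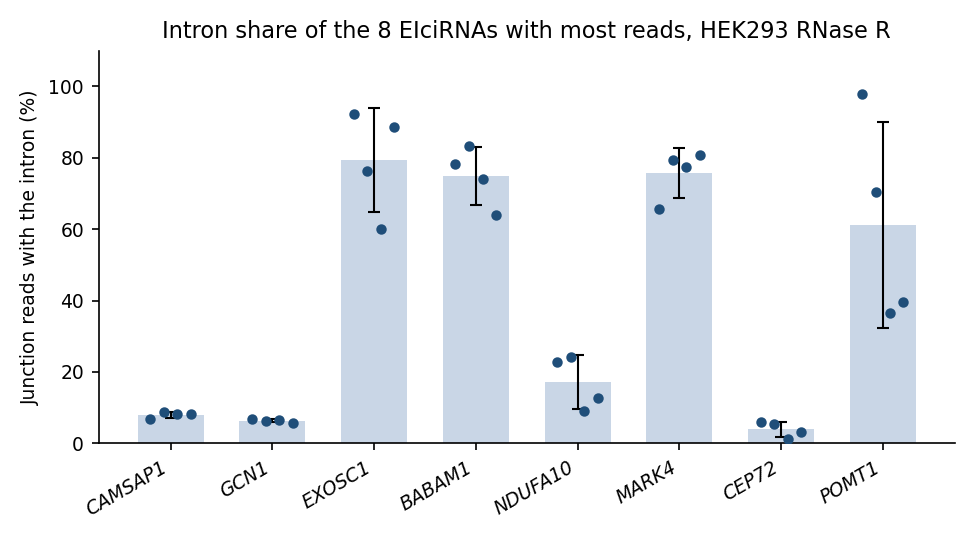
Share of back-splice junction reads that held the intron, in percent, for the 8 EIciRNAs with the most reads in HEK293. Bars are means, error bars SDs and points the 4 RNase R libraries, and EXOSC1, BABAM1 and MARK4 lie between 60.0% and 92.4% in every library whereas CAMSAP1, GCN1 and CEP72 reach at most 8.80%.

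EIciRNAs were a small part of the circRNA pool in HEK293. They took 0.840% ± 0.083 of the junction reads (SD, n = 4), and 1824 EIciRNAs from 1330 host genes stood among 106998 circRNAs. That is 1.70% of circRNAs (95% exact binomial interval 1.63 to 1.78), and 1.14% when EIciRNAs with a single read were left out. Among circRNAs with at least 10 reads the share was 5.67%. Without replicate 4 the share among all circRNAs was 1.56%. The nuclear export receptor gene XPO1 hosted 9 EIciRNAs and the dynein heavy chain gene DNAH14 and the gene ENSG00000286192 hosted 7 each, followed by ETFA, FIRRE, MARK4 and NOP58 with 6 each. By contrast, 1014 host genes gave 1 each. EIciRNAs came from shorter circles, with a median genomic span of 1982.5 bp against 10779.5 bp for other circRNAs, and from circles with more reads, with a median of 16 against 3 over the 4 libraries. Circles with more reads have more chances to show an intron, so the difference in reads may come from detection alone. Among 853 such circles with at least 20 reads, the median share of reads with the intron was 4.08% (quartiles 1.61 and 10.3), and 49 circles held the intron in at least 50% of reads. Detection was sparse, with 1275 EIciRNAs in 1 library and 117 in all 4.

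The next comparison asked whether the introns kept in circles are also kept in linear poly(A)+ RNA. Introns listed by the authors as retained in linear RNA included 102 of the 1535 EIciRNA introns (6.64%), against 1202 of 77230 other introns within circRNAs (1.56%). The odds ratio was 4.50 (two-sided Fisher's exact test, p = 3.5e-32). An intron of C2orf49, a subunit of the tRNA ligase complex, was retained at a mean ratio of 0.809 over the 2 poly(A)+ libraries and was present in 17 of 17 reads of its circle on chromosome 2. An intron of RHOF, a small GTPase gene, was retained at 0.747 with 1 EIciRNA read, and one of SEC31B, a coat protein gene, at 0.706 with 1 EIciRNA read. NCK1, which encodes a signalling adaptor, had 26 of 28 circle reads with its intron and a mean ratio of 0.419, from 0.0 in one library and 0.839 in the other. Short introns are retained more often, and the odds ratio within introns under 1000 bp, a limit chosen after the data were seen, was 2.82. Random introns matched on length gave 46.9 retained introns on average and at most 77, so the observed 102 lay 2.18-fold above them (permutation p = 0.0001, the smallest these 10000 draws can give). They were not matched on expression or read depth, and circles with an EIciRNA form had a median of 16 reads against 3 for other circRNAs. Whether expression accounts for part of the excess was not tested. Among the 8 introns with a ratio in both poly(A)+ libraries and at least 20 circle reads, the numbers were too few to tell whether linear retention and circle share are related (Spearman's rho = -0.36, exact permutation p = 0.389; Pearson's r = -0.32, exact permutation p = 0.465; across introns, which are not independent replicates). The list held no ratio above 0 and below 0.1, so weaker retention was not measured here.

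EIciRNA introns were short. In HEK293 their median length was 578 bp, against 1193 bp for the other introns of the same circRNAs (1529 and 1917 introns, permutation test, two-sided p = 1e-05, the smallest possible). In SH-SY5Y the medians were 543 bp and 1337 bp (392 and 156 introns, permutation p = 1e-05, the smallest possible). Circles with only 1 intron, 738 of 1529 in HEK293 and 260 of 392 in SH-SY5Y, gave a kept intron but no other intron. These length comparisons and those of GC content below were therefore made over all circles, not within each circle. All annotated introns of the host genes had medians of 1782 bp in HEK293 and 1998 bp in SH-SY5Y. In circles with 2 introns the kept one was the shorter in 66.6% of cases (247 of 371), by a mean log2 length ratio of -0.73. Kept introns also lay near the junction. In circles with at least 3 introns, the kept one was the first or last in 72.6% (302 of 416, 95% interval 68.0 to 76.8), against 49.3% if each intron were equally frequent. The median exonic distance from the junction was 105 bases for kept introns and 187 bases for the others. Reads at the junction may reach only nearby introns, so this position may reflect detection, which was not tested. The HEK293 list gives at most 1 intron per EIciRNA, so the other introns are not shown to be spliced out. GC content depended on what kept introns were compared with. It was 44.4% against 43.2% in HEK293 (permutation p = 0.0362) and 44.1% against 40.8% in SH-SY5Y (permutation p = 0.00803), and neither difference passed against all introns of the host genes (0.48 points, p = 0.340, and 0.55 points, p = 0.355). Within 15 bins of intron length, compared after the data were seen, kept introns of HEK293 were 2.62 points lower on average instead (lower in 10 bins and higher in 5, permutation within bins, p = 0.0013), and SH-SY5Y had 0 bins with at least 20 introns of each kind. Introns, not libraries, were the units of these tests.

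**Figure D2:**
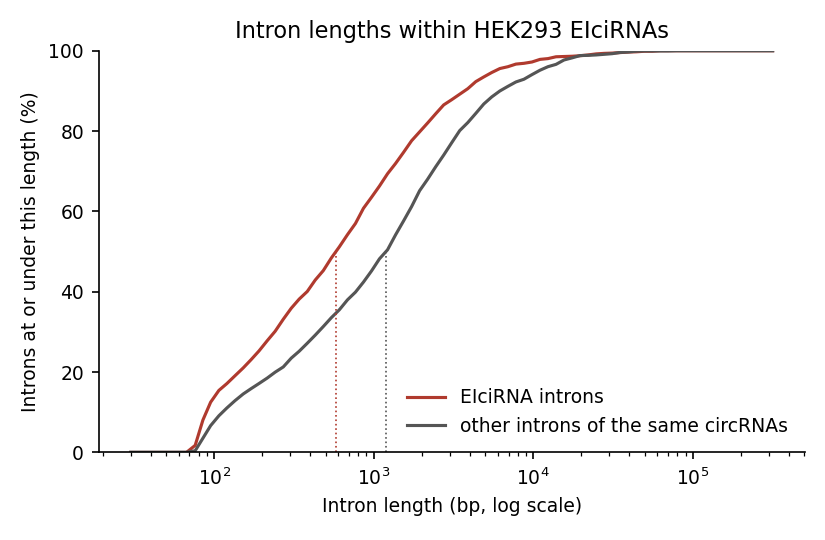
Cumulative percent of introns at or under each length in bp (log axis) for introns kept in HEK293 EIciRNAs and for the other introns of the same circRNAs. Dotted lines mark the medians of 578 bp and 1193 bp. Circles with a single intron contribute a kept intron only.

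DNA replication genes hosted EIciRNAs more often than other circRNA host genes. Of the 20 genes of this list with an intron-holding circRNA, 11 were EIciRNA hosts (55.0% against 13.8% of other genes, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000165 over 9 lists). They were the replicative helicase genes MCM3, MCM4, MCM5 and MCM6 with CDC45, the polymerase genes POLA1 and POLE, the ribonucleotide reductase gene RRM2, the checkpoint mediator gene CLSPN, the histone mRNA binding gene SLBP and UHRF1, which guides maintenance DNA methylation. Random gene sets matched on circRNA reads held 4.19 hosts on average (permutation p = 0.000400). UHRF1 had the most abundant of these EIciRNAs, with 45 of the 105 reads of its circle on chromosome 19 at 4941528 to 4941931 and reads in all 4 libraries, whereas MCM4, MCM6, RRM2 and SLBP rested on 1 read each. The hnRNP genes, whose proteins bind pre-mRNA, had 5 hosts among 19, the SR protein kinases 3 of 8 and the SR proteins 1 of 11, and none of the 8 remaining lists passed. SRSF1 binds purine-rich exonic sequences. Its motifs GGAGA and GAAGA occurred at 6.49 ± 0.17 per kb in the exons beside a kept intron and at 6.46 ± 0.21 per kb in other exons of the same circles (mean ± SE, 3040 and 1884 exons, permutation p = 0.898).

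EIciRNAs were compared between the cell lines to ask how far they are shared. CAMSAP1 led both lists, and BABAM1 was among the most abundant in both. A GCN1 circle was also in both, but its first listing in SH-SY5Y gave another intron (120155041 to 120155240) than HEK293 did (120155431 to 120155591). In SH-SY5Y, 32 EIciRNAs were listed with more than 1 intron over the libraries, and whether this circle was among them was not examined. Of the 384 EIciRNAs of SH-SY5Y, 255 had the same circle among the HEK293 EIciRNAs (66.4%, 95% exact binomial interval 61.4 to 71.1), and 351 (91.4%) were among all HEK293 circRNAs. By intron alone the share was 59.9%, by host gene it was 75.1%, and without HEK293 replicate 4 it was 58.9%. From the HEK293 side, 88 of the 117 EIciRNAs seen in all 4 libraries were also in SH-SY5Y (75.2%), against 62 of the 1275 seen in 1 library (4.86%).

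The knockdown asked what SRSF1, an SR protein that binds exons and promotes splicing, does to gene expression, intron retention and EIciRNAs. SRSF1 itself (ENSG00000136450, chromosome 17, 58000919 to 58007346) was 8.65-fold lower, at 49.1 ± 5.9 CPM (counts scaled to library size; SD, n = 2) in shSRSF1 against 425 in shCtrl (log2 fold change -3.11, SE 0.30, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.9e-07). The gene for the secreted growth factor binding protein IGFBP5 fell 10.5-fold (log2 fold change -3.40, SE 0.54, edgeR adjusted p = 0.00103) and that for nestin, NES, an intermediate filament protein of progenitor cells, fell 8.69-fold (-3.12, SE 0.53, edgeR adjusted p = 0.00148). LGR5, a receptor that strengthens Wnt signalling, fell 6.43-fold, from 111 to 17.2 CPM, and the transcription factor genes SNAI2 and GBX2 fell 6.60-fold and 5.83-fold. OLMALINC, a long noncoding RNA, and TYSND1, a peroxisomal protease gene, fell 7.43-fold and 5.80-fold. In the other direction, the transcription factor genes POU2F2 and ONECUT3 rose 10.2-fold and 7.20-fold (log2 fold changes 3.35, SE 0.56, and 2.85, SE 0.59). VSTM2L, PAMR1, BSPRY, the amino acid transporter gene SLC6A17 and the natriuretic peptide receptor gene NPR2 rose by 2.71 to 3.30 on the log2 scale. NME1-NME2, a readthrough transcript, rose by 3.70, which is uncertain because it shares its exons with NME1 (log2 fold change -0.62) and NME2 (-0.15), neither of which passed.

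Across genes, 63 were called higher and 124 lower of 16663 tested (edgeR, adjusted p under 0.05; 2087 at an unadjusted p under 0.05). With 1 control library, the spread came from the 2 shSRSF1 libraries alone, and the control was assumed to vary like them, which could not be checked. The count depended on the setting. Scaling by library size only gave 8 higher and 34 lower, DESeq2 gave 42 higher and 55 lower, no low-count filter gave 170 and 238, and a stricter filter gave 6 and 26. SRSF1, NME1-NME2, POU2F2, PAMR1, IGFBP5, NES, OLMALINC, LGR5 and TYSND1 kept their calls under every one of these settings, whereas VSTM2L, ONECUT3, BSPRY, SLC6A17 and NPR2 lost theirs with library size scaling and with the stricter filter, NPR2 also under DESeq2 and median-of-ratios scaling, and SNAI2 with the stricter filter. Without shSRSF1 replicate 1 the log2 fold changes of IGFBP5, NES and GBX2 were -4.12, -3.75 and -3.16, and without replicate 2 they were -2.78, -2.57 and -2.10, with SLC6A17 at 1.96, each against 1 control library and without a test.

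Among 18 gene lists fixed beforehand, 2 were higher after knockdown with the preset correlation, and 0 passed with fry. The test with an estimated correlation had 1 residual degree of freedom, so hardly any list can pass it and it cannot decide. Of the 21 measured genes of the integrated stress response and endoplasmic reticulum (ER) stress, 18 had positive fold changes and 2 rose, 5 when adjusted over the list alone (camera with a preset correlation, adjusted p = 1.2e-05; adjusted p = 0.916 with an estimated correlation). The ER chaperone gene HSPA5 rose 2.12-fold, from 466 to 985 CPM (log2 fold change 1.08, SE 0.27, edgeR adjusted p = 0.0442), and its co-chaperone gene DNAJB9 rose 4.69-fold (2.23, SE 0.49, edgeR adjusted p = 0.0220). HERPUD1, which acts in ER-associated degradation, and the lectin chaperone gene CALR had log2 fold changes of 1.33 and 0.86 without passing. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and were listed as a check of the poly(A) selection, had positive values in 14 of 15 with 0 called and 0 when adjusted over the list alone (camera adjusted p = 0.00410; adjusted p = 0.916 with an estimated correlation). H3C10 was at 1.59 and H2AC11 at 1.52 without passing. Among lists that did not pass, HNRNPC, an hnRNP that coats nascent transcripts, fell 2.09-fold, from 863 to 412 CPM (log2 fold change -1.07, SE 0.26, edgeR adjusted p = 0.0350). HMGCS1 of cholesterol synthesis fell 2.79-fold, and the vasodilator peptide gene ADM and the synaptic vesicle gene SYP rose 4.05-fold and 5.34-fold. HNRNPC, HSPA5 and SYP lost their calls under DESeq2, these and DNAJB9 under median-of-ratios scaling, and these, HMGCS1 and ADM under scaling by library size only and with the stricter filter (adjusted p from 0.0665 to 0.130 with that filter). Without shSRSF1 replicate 2, DNAJB9 was at 1.55 and ADM at 1.57.

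Intron retention in linear RNA after knockdown was read from the authors' deposited table, which gives an IR ratio per intron (intron depth over intron depth plus spliced reads) and p-values for the pooled libraries. These p-values treat reads as independent and hold no spread between libraries, so they cover counting error only, as do the counts of higher and lower introns built on them. Introns in hnRNP and SR protein genes were called more often than other introns in the authors' deposited table. With p-values for counting error only, introns with more reads are called more easily in either direction. The Fisher's exact tests of these lists were not matched on intron depth or expression. Whether depth accounts for part or all of the excess was not tested. Of 21 introns in hnRNP genes, 13 had a higher IR ratio in shSRSF1 (Fisher's exact test against all other introns, Benjamini-Hochberg adjusted p = 1.9e-07 over 15 lists) and 4 a lower one (adjusted p = 0.0622). An intron of HNRNPC rose from 0.0235 to 0.139 and one of HNRNPAB from 0.264 to 0.422, whereas one of HNRNPA1 fell from 0.431 to 0.202 and one of HNRNPL from 0.138 to 0.0869, all in the authors' deposited table. Of 8 introns in SR protein genes, 4 were higher (Fisher's exact test, adjusted p = 0.0421) and 2 lower (adjusted p = 0.145). The 4 include an intron of SRSF1 itself, the target of the hairpin, which rose from 0.148 to 0.255 in the authors' deposited table. Its intron depth fell from 379 to 73.6 and its spliced reads from 2135 to 215, so the higher ratio came with less intron RNA. The list was not tested without this intron. Introns of one gene are not independent in these tests. The largest changes in the authors' deposited table rested on 0 to 102 spliced reads per hairpin. The intron of MYO15B went from 0.0110 to 1.0 and that of COL27A1, a fibrillar collagen gene, from 0.0243 to 0.734, one of AGAP2 from 0 to 0.70, 2 introns of the DNase gene DNASE1L2 from 0.156 to 0.846 and from 0.131 to 0.801, and 3 introns of CCDC78 also rose. The complement component gene C8G went from 1.0 to 0.167, the meiotic cohesin gene REC8 from 0.656 to 0.0588, the receptor kinase gene FLT4 from 0.449 to 0.0263, PRSS23 from 0.596 to 0.188, TRAF2 from 0.646 to 0.262, AC093512.2 from 0.416 to 0.0417 and 2 introns of MXRA8 from 0.711 to 0.279 and from 0.791 to 0.362 in the authors' deposited table. MYO15B, COL27A1, AGAP2, C8G and CCDC78 carry the authors' warnings of low cover or low splicing, and FLT4, PRSS23, TRAF2, AC093512.2 and HNRNPC those of uneven cover. The introns named for HNRNPC, HNRNPAB, HNRNPA1, HNRNPL, SRSF1, FLT4 and PRSS23 overlap a known exon per the authors' deposited table.

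**Figure D3:**
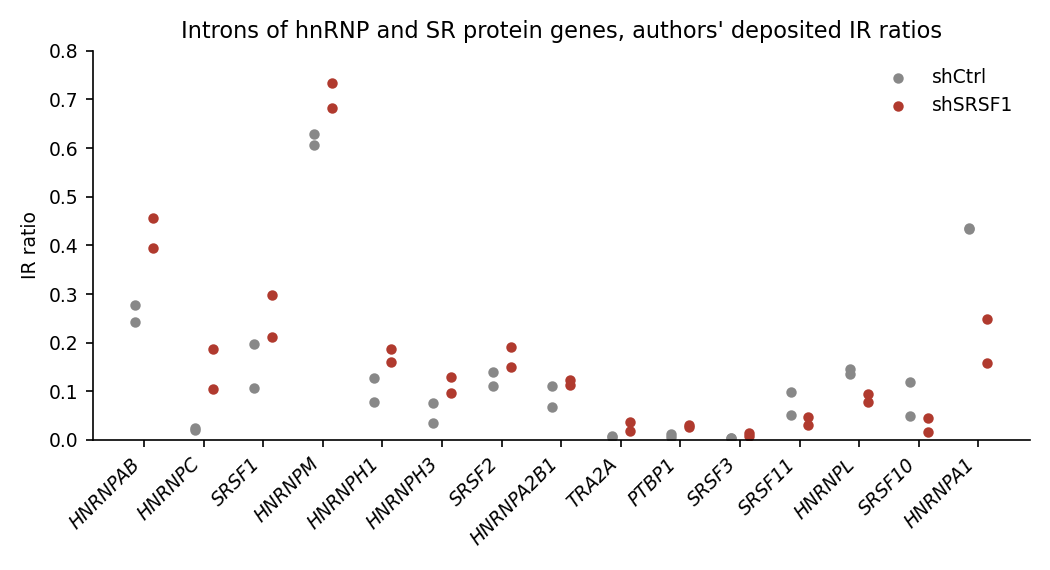
IR ratio (0 to 1) of 1 intron per hnRNP or SR protein gene, the one with the smallest p in the authors' deposited table among called introns, with a point for each of the 2 shCtrl and 2 shSRSF1 libraries. HNRNPAB, HNRNPC and SRSF1 lie higher in shSRSF1, and HNRNPA1 lies lower.

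In total, 1175 introns were higher and 459 lower of 11390 in the authors' deposited table (their p-values, doubled because they are one-sided, then Benjamini-Hochberg adjusted, for counting error only). With an IR ratio difference of at least 0.1 as a further condition, 439 were higher and 148 lower, and among the 4408 introns without a warning 570 were higher and 272 lower. Library values do not overlap between hairpins for 99.4% of the introns in the authors' deposited table, where chance gives 33.3%, so it holds preselected introns and the counts do not describe all introns. The median IR ratio over these introns was 0.0329 and 0.0387 in the shSRSF1 libraries and 0.0281 and 0.0265 in the shCtrl libraries. Whether a difference between libraries in unspliced RNA or poly(A) selection gave part of the excess of higher introns was not tested. EIciRNA introns of HEK293 made up 210 of the introns in the authors' deposited table. Of these, 21 were higher (10.0% against 10.3% of other introns) and 20 were lower (9.52% against 3.93%, odds ratio 2.58, Fisher's exact test, adjusted p = 0.00096 over 2 tests). Introns of ZMYND19 and of CSTF3, a pre-mRNA cleavage factor gene, were among the lower ones, from 0.166 to 0.0592 and from 0.136 to 0.0525. Both overlap a known exon per the authors' deposited table. Introns of UBL5, a splicing-associated ubiquitin-like gene, and of RBM28 were among the higher ones, from 0.0320 to 0.0932 and from 0.208 to 0.473 in the authors' deposited table. Among called introns, 48.8% of EIciRNA introns and 27.6% of others were lower (Fisher's exact test, odds ratio 2.5, p = 0.00447).

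EIciRNAs themselves were then compared between hairpins. CAMSAP1 again gave the most signal, at 23.2 and 244 in the 2 shCtrl libraries and 36.2 and 291 in the 2 shSRSF1 libraries (deposited scaled junction reads). A circle of DAP3, a mitochondrial ribosomal protein gene, was at 6.06 and 8.90 in shCtrl and 21.6 and 25.6 in shSRSF1 (log2 fold change 1.55, SE 0.65, limma on log2(value + 1)). One of FARSA, a phenylalanine tRNA synthetase subunit gene, was at 12.1 and 17 in shCtrl and 31.1 and 37.3 in shSRSF1 (1.19, SE 0.58). Neither passed, nor did CEP72 (2.58, SE 1.71), GCN1 (-2.85, SE 2.43), UHRF1 (-1.60, SE 1.89) or MRPL4 (-0.67, SE 0.71). The values of GCN1 and UHRF1 came from 0 reads in shSRSF1 replicate 1, while replicate 2 differed by 0.72 and 0.90 in the other direction, and that of CEP72 came from 0 reads in shCtrl replicate 1 (0.28 in replicate 2). Of the 1167 EIciRNA entries listed, 25 had enough reads to test. limma called 0, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.996, and edgeR and DESeq2 on the recovered reads also called 0. Few entries were shared between libraries: 937 were seen in 1 library and 19 in all 4, and a circle of RBM41 had a signal of 117 in shCtrl replicate 1 and was listed at 0 in the other 3.

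Day 3 against day 0 of SH-SY5Y asked what differentiation changes first. Per the labels, retinoic acid was given in 1% serum and cells were otherwise grown in 10%, so the effects of retinoic acid and of less serum cannot be separated in any comparison with day 0. The 2 largest increases were in genes that degrade retinoic acid. CYP26A1, a retinoic acid hydroxylase gene, had 0 counts on day 0 and 568 ± 267 CPM on day 3 (SD, n = 2), at least 4203-fold higher against a floor of 3 counts over the group. CYP26B1, its homologue, had 1 count on day 0 and 2586 ± 304 CPM on day 3 (count ratio 57069, 95% counting interval 10242 to 2254130). The retinal reductase gene DHRS3 reached 306 ± 89.1 CPM against 0.228 ± 0.070 (log2 fold change 10.32, SE 0.53). NTRK2, the receptor for the neurotrophin BDNF, rose 981-fold (9.94, SE 0.41) and RET, the receptor for GDNF ligands, rose 41.2-fold, to 3992 ± 34.6 from 96.9 ± 50.3 CPM (5.36, SE 0.49, edgeR adjusted p = 0.00046). COLCA1, SLC6A17, TXK and POU2AF2 had 0 counts on day 0 and were at least 893-fold, 228-fold, 106-fold and 100.1-fold higher. MYC, the growth-promoting transcription factor gene, fell 19.8-fold, from 157 ± 15.3 to 7.91 ± 3.92 CPM (-4.31, SE 0.40, edgeR adjusted p = 0.000484). The synapse organiser gene CBLN4 fell 162-fold, the proneural factor gene NEUROG2 24.9-fold, the muscarinic receptor gene CHRM2 30.8-fold and NELL1 45.2-fold, and VSNL1, SLITRK5 and SALL4 fell by 4.19 to 4.35 on the log2 scale.

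Among 27 fixed lists, 6 were higher and 7 lower on day 3 (camera with a preset correlation). None of the 13 passed with an estimated correlation, where the smallest adjusted p was 0.0749. That test had 3 residual degrees of freedom, so hardly any list can pass it. With fry, 5 of the 13 passed: retinoic acid response, HOX, neuronal maturation, mitotic and adrenergic state genes. Of 22 retinoic acid response genes, 12 rose over all genes, and 14 rose and 2 fell when adjusted over the list alone (camera adjusted p = 1.6e-37; 0.0749 as the adjusted p with an estimated correlation). HOX genes, which set axial identity, rose in 4 of 12, or 7 adjusted over the list alone (camera adjusted p = 2.3e-05; adjusted p = 0.110 with an estimated correlation), led by HOXD9 at 7.57-fold (2.92, SE 0.30) and HOXD8 at 4.48-fold. Neuronal maturation genes rose in 4 of 37 and fell in 1, or 8 and 2 adjusted over the list alone (camera adjusted p = 4.4e-05; 0.110 as the adjusted p with an estimated correlation). The granin gene SCG2 rose 10.0-fold, and the axonal adhesion gene CNTN1 fell 6.73-fold. Mitotic genes fell in 4 of 28, or 24 adjusted over the list alone (camera adjusted p = 1.4e-18; 0.110 as the adjusted p with an estimated correlation): the kinesin gene KIF20A 2.94-fold, the anaphase activator gene CDC20 2.77-fold, the kinase gene PLK1 2.72-fold and the cyclin gene CCNB2 2.30-fold. Ribosomal protein genes were all negative, 38 of 38, with 0 called, also adjusted over the list alone (camera adjusted p = 2.4e-08; adjusted p = 0.613 with an estimated correlation). Genes of the adrenergic neuroblastoma state fell in 3 of 20 and rose in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00807; adjusted p = 0.237 with an estimated correlation), with EYA1 down 3.48-fold and DACH1 up 5.48-fold. Of 14 Notch pathway genes 1 fell and 2 rose, or 4 and 2 adjusted over the list alone: the ligand-like gene DLK1 fell 18.1-fold, and the target genes HES1 and HEY1 rose 8.38-fold and 2.75-fold (camera adjusted p = 0.0190, down; adjusted p = 0.409 with an estimated correlation). Core spliceosome, hypoxia and hnRNP genes were lower as lists, with 0, 1 and 0 called (2, 2 and 0 adjusted over the list alone). Catecholamine, cholesterol and stress response genes were higher, with 1, 0 and 0 called (4, 1 and 0 adjusted over the list alone). These 6 lists had adjusted p between 0.499 and 0.65 with an estimated correlation.

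Across genes, 310 rose and 138 fell on day 3 of 16521 tested (edgeR; 2756 at an unadjusted p under 0.05). The count was 981 with DESeq2 and 1197 with no low-count filter. Without day 0 replicate 1 or 2 it was 146 or 181, without day 3 replicate 1 or 2 it was 223 or 206, and without day 6 replicate 1 or 2 it was 679 or 696. CYP26A1, CYP26B1, DHRS3, NTRK2, RET, HOXD9, HOXD8, SCG2, CNTN1, DLK1, NELL1, NEUROG2 and MYC kept their calls in all of these. Without any 1 of the day 0 or day 3 libraries, KIF20A (log2 fold changes from -1.49 to -1.62), CCNB2 (-1.05 to -1.34), HEY1 (1.28 to 1.66) and SALL4 (-3.78 to -4.72) did not pass. CDC20 (-1.27 to -1.54) and PLK1 (-1.18 to -1.61) did not pass without day 0 replicate 1 or a day 3 library, nor did CHRM2 (-4.29 to -5.63) and EYA1 (-1.53 to -1.999) without day 0 replicate 2 or a day 3 library. HES1 (2.62 and 3.71) and DACH1 (2.62 and 2.30) did not pass without day 0 replicate 1 or 2. CBLN4 did not pass under DESeq2, SALL4 and CCNB2 not with library size scaling, and CCNB2 not with the stricter filter.

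Day 6 against day 0 gave the later state. CYP26B1 stood at 3505 ± 182 CPM and CYP26A1 at 690 ± 48.5 CPM (SD, n = 2), the second at least 5062-fold above its day 0 floor. NTRK2 was 1220-fold higher (log2 fold change 10.25, SE 0.41), DHRS3 rose by 10.70 (SE 0.53) and TGM2, a transglutaminase gene and textbook retinoid target, rose 107-fold (6.74, SE 0.58, edgeR adjusted p = 0.000299). CBLN4 had 0 counts on day 6 and was at least 382-fold lower. NEUROG2 fell 42.4-fold, the angiotensin receptor gene AGTR1 36.2-fold, the netrin receptor gene UNC5D 35.2-fold and MYC 22.4-fold (-4.49). Of 28 mitotic genes, 26 fell, 28 when adjusted over the list alone (camera adjusted p = 1.3e-28; adjusted p = 0.119 with an estimated correlation). The cyclin-dependent kinase gene CDK1 fell 3.97-fold, and TOP2A, CDC20 and PLK1 fell by 1.93, 1.77 and 1.76 on the log2 scale.

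Retinoic acid response genes rose in 13 of 22, or 14 adjusted over the list alone (camera adjusted p = 1.75e-30; adjusted p = 0.0850 with an estimated correlation). HOX genes rose in 5 of 12, or 6 adjusted over the list alone (camera adjusted p = 7.2e-06; 0.124 as the adjusted p with an estimated correlation), with HOXD9 11-fold higher. Neuronal maturation genes rose in 8 of 37 and fell in 3, or 16 and 3 adjusted over the list alone (camera adjusted p = 0.000451; 0.135 as the adjusted p with an estimated correlation), and those that fell included CNTN1 (13.3-fold) and the glutamate receptor gene GRIA2 (log2 fold change -2.15). Adrenergic state genes fell in 6 of 20 and rose in 1, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.160 with an estimated correlation), with EYA1 at -2.37 and SOX11 at -1.71. RNA processing lists were lower as well with the preset correlation. With fry, the hnRNP, core spliceosome, SR protein, circRNA biogenesis, ribosomal protein, DNA replication and hypoxia lists did not pass (adjusted p from 0.194 to 0.459). All 24 hnRNP genes had negative values with 0 called, also adjusted over the list alone (camera adjusted p = 0.000144; 0.582 as the adjusted p with an estimated correlation). Core spliceosome genes fell in 2 of 31, or 5 adjusted over the list alone, SNRPA1 by 1.5 and SNRPA by 1.11 on the log2 scale (camera adjusted p = 0.000451; adjusted p = 0.582 with an estimated correlation). The 14 SR protein genes had 0 called, also adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.582 with an estimated correlation), SRSF1 among them at -1.05 without passing. Of 22 circRNA biogenesis factors, QKI, an RNA-binding protein gene whose product promotes circle formation, fell 2.64-fold (-1.40, SE 0.28) and was the 1 called, also adjusted over the list alone (camera adjusted p = 0.0408; adjusted p = 0.582 with an estimated correlation). Ribosomal protein genes (38 of 38 negative, 0 called, also adjusted over the list alone), DNA replication genes (1 of 28 fell, 3 adjusted over the list alone, with RRM1 down by 1.18) and hypoxia genes (3 of 17, or 4, with LDHA down by 1.98) were also lower, with adjusted p of 0.620, 0.633 and 0.582 with an estimated correlation. The acetylcholinesterase gene ACHE rose 4.82-fold (2.27, SE 0.44).

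On day 6, 645 genes rose and 461 fell of 16521 tested (edgeR; 3984 at an unadjusted p under 0.05). The count was 1911 with DESeq2, 2270 with no low-count filter, 425 and 342 without day 0 replicate 1 or 2, and 653 without day 6 replicate 2. Without day 6 replicate 1 the balance turned, with 734 higher and 913 lower. QKI (log2 fold changes from -1.21 to -1.43) and SNRPA1 (-1.24 to -1.52) did not pass without day 0 replicate 1 or 2 or day 6 replicate 2. ACHE did not pass without day 0 replicate 2 (1.67), nor LDHA without day 0 replicate 2 or day 6 replicate 2 (-1.05 and -1.83). SNRPA and RRM1 did not pass when the fit held the compared days only. Of the 6 libraries left out in turn, SNRPA passed only without day 6 replicate 2 and RRM1 only without day 0 replicate 1, with values from -0.90 to -1.31 and from -0.88 to -1.30 in the others.

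**Figure D4:**
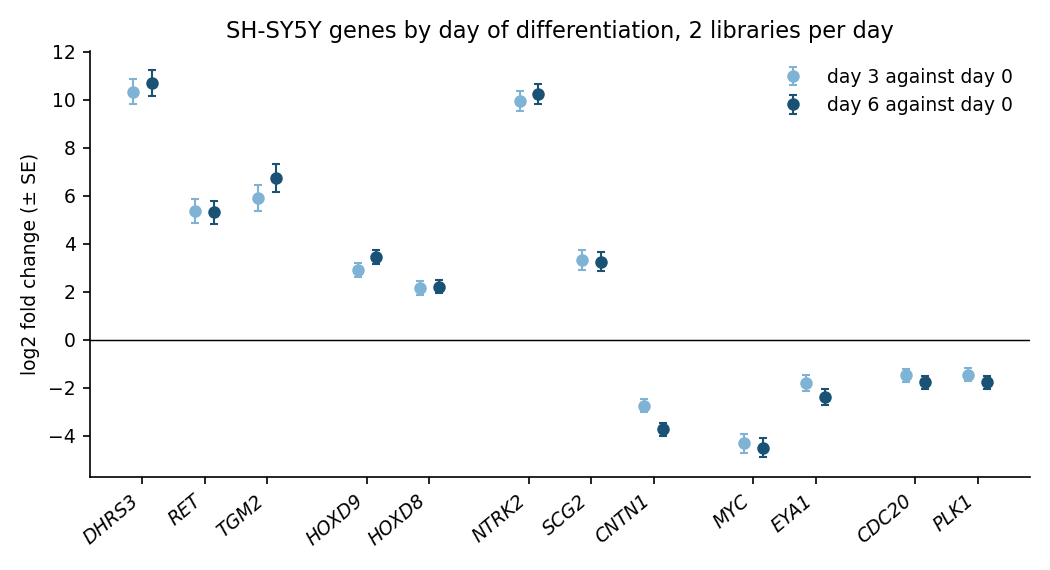
Log2 fold change (± SE, edgeR, 2 libraries per day) of 12 SH-SY5Y genes on day 3 and on day 6 against day 0, grouped as retinoic acid response, HOX, neuronal maturation, adrenergic and mitotic genes. DHRS3, RET, TGM2, HOXD9, HOXD8, NTRK2 and SCG2 lie above 0, and CNTN1, MYC, EYA1, CDC20 and PLK1 lie below 0 on both days.

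Between day 6 and day 3 single genes were not separable. Mitotic genes were lower as a list, with 27 of 28 negative (camera adjusted p = 2.2e-15), as were DNA replication genes with 27 of 28 (1.35e-07), hnRNPs with 23 of 24 (5.3e-06) and SR proteins with 13 of 14 (0.000167). Mesenchymal state genes were higher, with 15 of 17 positive (camera adjusted p = 5.1e-06), and 6 of 6 Schwann and glial genes were positive (0.000721). None passed with fry. With an estimated correlation none passed either, and the adjusted p of these 6 lists ran from 0.358 to 0.502 with an estimated correlation. Cholesterol, adrenergic and circRNA biogenesis genes were also lower, and cholinergic, p53 target, Notch and mitochondrially encoded genes, the last listed as a measure of RNA quality, higher (camera adjusted p from 0.00272 to 0.0443; adjusted p from 0.358 to 0.502 with an estimated correlation). No list had a called member over all genes. Adjusted over the list alone, 1 fibroblast and matrix gene fell, in a list that did not pass (camera adjusted p = 0.128), and every other list had 0. Over all genes edgeR called 0 genes, with 367 at an unadjusted p under 0.05, DESeq2 called 1, edgeR with no low-count filter called 26, and edgeR without day 3 replicate 1 called 2.

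EIciRNAs during differentiation were the last question. The DAP3 circle on chromosome 1 at 155725382 to 155726019 fell on day 6, from 10 and 24 to 1 and 5 reads (-3.26, SE 0.91, edgeR adjusted p = 0.0248). A circle of MGAT5, which encodes an N-glycan branching enzyme, had 3 and 3 reads on day 0 and 31 and 38 on day 6 (2.66, SE 0.92, edgeR adjusted p = 0.113), and one of ASAP1 had 2.14 (SE 0.94); neither passed. CAMSAP1 was most abundant on each day, with 84 and 400, 111 and 252, and 200 and 371 reads. Of 384 EIciRNAs, 138 were listed on day 0, 164 on day 3 and 299 on day 6, 64 on all 3 days and 156 on day 6 only, while day 6 also had the most EIciRNA reads. Only the 64 listed on all 3 days entered the tests, and 51 of these had enough reads, so those listed on day 6 only were not tested. Entries were matched by circle. Of the 384, 32 were listed with more than 1 intron over the libraries, so a tested entry may compare different introns. Among the 51, DAP3 was the 1 call on day 6 (9 at an unadjusted p under 0.05), and edgeR called 0 between day 6 and day 3 (4 at an unadjusted p under 0.05, smallest adjusted p 0.616, DESeq2 0). For day 6 the count was 0 with at least 10 mean reads and without day 0 replicate 1, day 6 replicate 1 or day 6 replicate 2, and 2 without day 3 replicate 1. Without day 0 replicate 2, DAP3 did not pass and the 1 call was higher, not lower.

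Host genes of EIciRNAs were placed within the gene expression changes. The median log2 fold change of 1311 HEK293 host genes after SRSF1 knockdown was 0.03, at percentile 7.99 of random lists matched on expression (95% of lists from 0.02 to 0.08) and at percentile 0.35 when gene length was matched too. The 896 hosts of the knockdown experiment's own EIciRNAs were at 0.04, percentile 27.1. The 341 SH-SY5Y hosts were at -0.06 on day 3, percentile 22.2, and at -0.13 on day 6, percentile 2.11, or 18.2 when gene length was matched. HEK293 hosts, measured in SH-SY5Y, were at -0.11 on day 3 and -0.17 on day 6, below each of 10000 random lists. On day 3, 10 SH-SY5Y hosts rose and 0 fell, against 9.68 called in random lists, and on day 6, 16 rose and 12 fell, against 24.8. Fewer HEK293 hosts were called than in random lists, 18 against 40.2 on day 3 and 65 against 98.6 on day 6 (percentiles 0.015 and 0.02). These percentiles describe these libraries and are across genes, which are not independent replicates.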

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

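In this part, the tests of intron length and of the number of EIciRNAs were chosen after the results were seen, and those of EIciRNA introns in the retention table before. HEK293 RNase R replicate 2 stood apart from the other 3 libraries in total junction reads, with 407173 against 306722 to 313296, while 23 quantities were examined in this way and chance sets about 1 in 20 apart.

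EIciRNA introns were shorter than the other introns of the same circRNAs in both cell lines, compared over all circles. If reads only reached introns near the junction, introns at equal distance should not differ, but in 95 circles with 2 introns and flanking exons within 20 bases of each other in length the mean log2 length ratio was -0.75 (SE 0.207, permutation p = 0.00043). Distance from the junction therefore falls short as the whole cause. The 1433 EIciRNA introns not listed as retained in linear RNA had a median of 620 bp against 1193 bp, but that list holds no ratio above 0 and below 0.1, so reads from linear RNA with weakly retained introns cannot be told apart. A lower chance of reading through long introns in circles, and a preference for short introns in the cell, also remain open and were not tested, so the lengths may reflect any of these.

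After the knockdown, shSRSF1 replicate 2 listed 765 EIciRNAs and shCtrl replicate 2 listed 506. Thinned to 1026 reads each, they still listed 434 and 375 on average, so more reads are not the whole cause. Among EIciRNAs with at least 2 reads the numbers were 446 and 463, since 319 of those in the shSRSF1 library (41.7%) rested on a single read against 43 in the shCtrl library (8.50%). The excess may therefore come from single-read entries, whose origin in handling or biology was not tested. Replicate 1 pointed the other way at equal reads, with 91 against 113, and with 1 further pair of libraries an effect of the knockdown cannot be told apart from a difference between libraries.

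EIciRNA introns were more often lower than other introns in the authors' deposited retention table, 20 of 210. Random introns of that table matched on IR ratio and depth gave 12.8 lower introns on average, and 2.84% of draws gave 20 or more. Random introns matched on length gave 10.1, and 0.26% of draws gave as many. Matched separately, neither IR ratio with depth nor length gave the whole difference on average. They were not matched together or on expression, so a combination of these properties remains possible. The number is small and the table holds preselected introns, so the pattern may be a property of that selection, which was not tested, and an effect of SRSF1 on these introns remains a hypothesis.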

How the results depend on the processing

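Alternatives added after the data were seen are named as added, here or in the methods, and the others were chosen before the data were examined. Of all alternative values, 1480 kept their direction and their side of the threshold or their size, 1386 of them single named genes or circles. A call was lost in 193 (189 of them named genes or circles), 63 moved (11 of them named genes or circles), 1 gained a call and 1 reversed. Most values that moved were therefore main results, such as numbers of calls, and the 1480 mainly describe named genes and circles. Unless a cause is given, the cause was not tested.

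For the fixed gene lists, camera with an estimated correlation passed 0 lists in each of the 4 gene comparisons, where the preset correlation passed 2, 13, 12 and 13, and fry passed 0 after knockdown, 5 on day 3, 5 on day 6 and 0 between day 6 and day 3. With 1 residual degree of freedom after knockdown and 3 in SH-SY5Y, the estimated setting lets hardly any list pass, so its 0 cannot decide. For the stress response list after knockdown the estimated correlation was -0.048, below the preset 0.01. On day 6 it was 0.470 for hnRNP, 0.417 for core spliceosome and 0.814 for ribosomal protein genes, above the preset. The lists that passed with fry on day 3 and on day 6 were retinoic acid response, HOX, neuronal maturation, mitotic and adrenergic state genes. The 187 knockdown genes became 104 with median-of-ratios scaling, 42 with library size only, 97 with DESeq2, 408 with no low-count filter, 32 with a stricter filter and 1907 when both identical control columns were counted as libraries (added), which removes spread by construction. Leaving out a shSRSF1 library left 1 against 1, a value with no test. DESeq2 gave 981 genes on day 3 against 448, 1911 on day 6 against 1106 and 1 between day 6 and day 3 against 0, and no low-count filter gave 1197, 2270 and 26. Leaving out each library gave 146 to 696 genes on day 3, 342 to 1647 on day 6 and 0 to 2 between them. Where a day kept 1 library, it was assumed to vary like the others.

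With the replicate number as a replicate block, 1007 genes were called on day 3, 2306 on day 6 and 0 between them. The block called 0 EIciRNAs after knockdown, 3 on day 6 (2 higher and 1 lower) and 0 between day 6 and day 3. With 2 replicates, the numbers are not taken to pair the libraries, although deviations of same-numbered SH-SY5Y libraries correlated at 0.201, 0.170 and 0.362 across genes. No paired analysis was possible because the 2 shCtrl gene columns are identical, and for the catalogue, the intron properties, the sharing and the retention table because they come from no test between libraries.

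The EIciRNA share of 1.70% was 1.14% with at least 2 reads, 5.67% among circRNAs with at least 10 reads, which leaves out circles too shallow to show an EIciRNA, and 1.56% to 1.74% without 1 library (added). The GC differences of 1.2 and 3.25 points became 0.48 and 0.55 against all introns of the host genes and did not pass, and within bins of intron length the HEK293 difference reversed to -2.62 (added), since kept introns are short and length was then held equal. The share of SH-SY5Y EIciRNAs found in HEK293 was 59.9% by intron, 75.1% by host gene and 58.9% to 64.6% without 1 HEK293 library (added), which shortens the HEK293 list. For SH-SY5Y EIciRNAs on day 6, a mean of at least 10 reads gave 0 calls against 1, and leaving out libraries gave 0 to 2. The 1634 introns called in the authors' deposited table became 587 with a difference of at least 0.1 and 842 without warnings, both by testing or keeping fewer introns. The percentile of HEK293 hosts after knockdown was 0.35 with gene length matched, against 7.99, and that of SH-SY5Y hosts on day 6 was 18.25, or 75.65 for the number of called hosts, against 2.11.

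Few EIciRNAs were tested, 25 of 1167 entries after knockdown and, in SH-SY5Y, 51 of the 64 listed on all 3 days among 384. Changes smaller than 8-fold and 4-fold were not simulated for these tests.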

Other observations

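The introns with the smallest p-values after SRSF1 knockdown were chosen after their values were seen. In the authors' deposited table, 4 introns of LONP1, which encodes the protease of the mitochondrial matrix, rose from 0.0332 to 0.430, from 0.0268 to 0.366, from 0.0375 to 0.368 and from 0.0319 to 0.340. They lie on chromosome 19 between 5692209 and 5696053, and 3 of the 4 carry the authors' warning of uneven cover. The gene itself had a log2 fold change of -0.71 (SE 0.35, edgeR adjusted p = 0.400). An intron of HSP90B1, an ER chaperone gene of the stress response list, rose from 0.0832 to 0.204, one of the ribosomal protein gene RPL13 from 0.0135 to 0.0293 and one of the tubulin gene TUBB4B from 0.0296 to 0.0680 in the authors' deposited table. HNRNPC, whose transcript fell 2.09-fold, held the intron with the smallest p of the authors' deposited table (2.58e-92 after doubling), with a warning of uneven cover and a known exon overlapping it.

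In SH-SY5Y, single genes outside the passing lists also moved. The interferon regulatory gene IRF9 rose by 1.51 on day 3 and by 2.24 on day 6 on the log2 scale (edgeR adjusted p = 0.0499 on day 3), and it did not pass on day 3 when any 1 day 0 or day 3 library was left out, with other scalings or with the stricter filter. The fibrillar collagen gene COL3A1 rose by 2.90 and 3.01, although its list did not pass (camera adjusted p = 0.164 and 0.0566) and it did not pass on day 3 without replicate 2 of day 3 (1.75) or without a day 0 library (2.58 and 3.30). On day 6 it did not pass without a day 0 library (2.69 and 3.39) or day 6 replicate 2 (2.27), and IRF9 not without day 0 replicate 1 (2.12). The cell cycle inhibitor gene CDKN1B rose by 1.27 and 1.17. It did not pass on either day without a day 0 library (1.08 and 1.47 on day 3), and not on day 3 without a day 3 library (1.35 and 1.19). Single-read entries made up 30.2%, 16.9%, 37.3% and 54.0% of the EIciRNAs of the 4 HEK293 RNase R libraries, and replicate 4, with the highest share, also listed the most EIciRNAs (971 against 562 to 644).

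Shares of circle reads with the intron fell with the size of the circle. Across 665 circles, Spearman's rho was -0.40 with the genomic span, -0.25 with the exonic distance from the junction and -0.18 with intron length (permutation p = 1e-05 each, the smallest possible). These are relations across circles, which are not independent replicates.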
